A study of Danio rerio with 8 samples.

How the data were processed

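Total RNA of zebrafish embryos was isolated with TRIzol, poly(A) RNA was purified on oligo(dT) beads, and stranded libraries were built with a KAPA kit, per the labels' protocols. The submitters' processing notes name cutadapt 1.13, Trimmomatic 0.36, HISAT2 2.0.5 and SAMtools 1.9 and the genome build Zv9. The read counter, its strand setting, the gene annotation and the gene lengths are not given in the sources used here. The authors deposited 4 tables of RPKM, read counts scaled by gene length and library depth, each with 33737 Ensembl gene identifiers and 1 value per gene for a group of 2 libraries. The tables carry no header, and each was matched to its group by the knockdown or wild-type tag and the age in its own name, which match the genotype and age labels of 1 group. For the control groups the tables and the genotype labels read wild type while the titles name a control morpholino; they were taken as the same embryos, which the sources used here do not state outright. The 8 samples were grouped by their titles. For the second knockdown library at 6 hpf the genotype label names ddx4xb while its title names ddx3xb, and the title was followed.

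RPKM scales each library to its reads, so a feature that takes many reads lowers the other values, and it also removes gene length, so that short features reach high values from few reads. The RPKM sums were 431798 for control at 2 hpf, 731302 for knockdown at 2 hpf, 461376 for control at 6 hpf and 473849 for knockdown at 6 hpf, and 12544, 12104, 14056 and 14237 genes reached 1 RPKM. Low values (under 0.3 RPKM) moved in steps of 2 sizes per table, as the mean of 2 libraries of unlike depth gives. The steps were read from ratios between tables (tolerance 0.0003 on the log2 scale) and gave the relative depth of the 8 libraries, with a deeper library 1.07, 1.21, 1.18 and 1.03 times the shallower one in the 4 groups. Per-library values were not rebuilt from them. Read worth was taken from 238 genes at 2 hpf and 280 at 6 hpf, under 0.3 RPKM in both tables of the age and on these steps. Their values were taken as single reads. An RPKM of 5 stood for about 78, 67, 46 and 40 reads at the 90th percentile of their read worth. At such genes counting error is small beside a 2-fold change at that level. The other genes compared need not share this read worth. Counting error is not replicate error, which stays unknown.

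A limma fit over replicates had been planned before the data were examined, with camera and fry for the gene lists. With 1 value per group none could be run, and the procedure fixed for that case was used. Genes with at least 1 RPKM in any table were kept (16217), ratios were taken as log2 of (RPKM + 1), genes were counted at a ratio of at least 2-fold, and the median of each gene list was set against 10000 random lists of the same size whose members were drawn from the same 1 of 20 bins of mean expression. A list was called outside where its median lay below or above the middle 95% of these, which describes these tables and tests no condition. Of 24 lists, 22 had at least 3 members in the comparison. They covered DEAD-box helicases, known maternal transcripts, first-wave zygotic genes, Nodal, BMP, FGF and Wnt signalling, neurectoderm, enveloping layer, yolk syncytial layer, primordial germ cells, activators of the zygotic genome, mRNA decay, translation factors, ribosomal proteins, cell cycle, p53, interferon and heat shock responses, the mitochondrial genome, erythroid cells, muscle and neurons, follicle and ovary, and genes used by every cell. Whole embryos were sampled, and no cell was classified.

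Genes were drawn for naming by a rule fixed beforehand: ddx3xb, up to the 8 largest rises and 8 largest falls per comparison among genes with at least 5 RPKM in the higher table, and up to 3 members per list with the largest ratio. At most 2 identifiers without a symbol were named per direction. The features 5_8S_rRNA and 5S_rRNA, pou5f3 and the members of lists added in the closing section were chosen after their values were seen. Symbols came from a table that matched 21939 of the 33737 identifiers and 12259 of the 16217 genes compared; some appear in upper case as that table gives them. The tables hold no coordinates, and none are given. Genes that can share reads with near-identical copies (heat shock genes, keratins, ribosomal RNA features) are uncertain one by one, as are overlapping and antisense genes.

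Classes by change over time used the mean of both arms: cleared (at least 5 RPKM at 2 hpf and a log2 change of -2 or below), activated (under 1 RPKM at 2 hpf, at least 3 RPKM at 6 hpf and a log2 change of 2 or more) and stable (at least 5 RPKM at both ages and a log2 change within 0.5 of 0). For the lists of the closing section, random lists matched on the mean change over time were also drawn. Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter or a filter of 5 RPKM, rescaling by the median ratio within each age, quantile normalization within each age, rescaling of each table to a sum of 1000000, thresholds of 1.5-fold and 4-fold, and classes set from 1 arm or at other changes. A rescaling to the same sum without the features above 5000 RPKM was added after the data were seen. The code was tested on simulated tables that held counting error only, with the same read worth for all genes of a table and no replicate error. The genes given a change had a mean of at least 5 RPKM. These results check the code and give no error rate for the deposited tables. Of the 100 genes given a 4-fold change, 100% were called at 2 hpf (12756 genes) and at 6 hpf (15296 genes), of the 100 given a 1.5-fold change 0% were called, and 0 unchanged genes were called. Lists of 20 unchanged genes fell inside the range in 97% of cases at 2 hpf and 95% at 6 hpf, and lists of 20 genes raised 1.5-fold lay above it in 100% of cases at both ages. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.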

Results

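Poly(A) RNA of whole zebrafish (Danio rerio) embryos was sequenced at 2 and 6 hours post fertilization (hpf), after injection of either a control morpholino, as the sample titles name it, or a morpholino against ddx3xb. A morpholino is a synthetic antisense oligomer that blocks the translation or the splicing of its target RNA, and ddx3xb encodes a DEAD-box RNA helicase of the DDX3 family. The 2 ages lie on either side of the maternal-to-zygotic transition, when RNA laid down in the egg is removed and the embryo's own genome is switched on. The 8 libraries fell into 4 groups of 2: control at 2 hpf, knockdown at 2 hpf, control at 6 hpf and knockdown at 6 hpf. The series also names embryos at 4 hpf, which were not analysed here. Expression was given in RPKM for 33737 Ensembl gene identifiers, with 1 value per gene for each group, so that every difference below compares 2 tables and has no replicate check, error or p-value. Steps in the low values put the depth of the libraries, relative to the deepest, at 1 and 0.935 for control at 2 hpf, 0.848 and 0.702 for knockdown at 2 hpf, 0.625 and 0.531 for control at 6 hpf, and 0.507 and 0.490 for knockdown at 6 hpf. An RPKM of 5 stood for about 497, 415, 248 and 212 reads in these groups at a gene of median read worth. That median is over 238 genes at 2 hpf and 280 at 6 hpf with low values, and need not hold for the genes compared. A total of 16217 genes reached 1 RPKM in at least 1 table and were compared as log2 ratios of (RPKM + 1), which understate the change of genes with low values. Genes are said to have risen or fallen where this ratio was at least 2-fold.

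The targeted transcript, ddx3xb (ENSDARG00000005774), was present in every group. At 2 hpf it stood at 273.9 RPKM in control and 250.8 RPKM in knockdown embryos, a log2 ratio of -0.13 that became 0.07 after rescaling by the median ratio. At 6 hpf it rose in the knockdown, with 141.0 RPKM in control and 321.8 RPKM in knockdown embryos (log2 ratio 1.18, and 0.97 after the same rescaling, just short of 2-fold). Its paralog ddx3xa (ENSDARG00000020573) followed the same course, with 102.7 and 84.3 RPKM at 2 hpf and 41.8 and 115.1 RPKM at 6 hpf. Neither gene's RNA reports on the amount of protein, and a morpholino need not lower the RNA of its target, so these values do not check the labels. Reads shared between the paralogs could not be told apart here.

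The comparison at 2 hpf asked how the knockdown changed the maternal RNA pool, as captured on oligo(dT) beads, before most zygotic transcription. A change in RNA amount could not be told apart from a change in capture. The tables were close to each other, with a Pearson correlation across the 16217 genes of 0.986, and 82 genes had risen and 153 had fallen in the knockdown. Transcripts of ribosomal proteins, the protein part of the ribosome, were higher as a group. Their median log2 ratio was 0.39 over 70 members, 64 of them above 0, with RPL35 at 53.3 RPKM in control and 107.1 RPKM in knockdown embryos, RPS25 at 117.3 and 210.4 RPKM, and RPL19 at 49.6 and 87.5 RPKM. First-wave zygotic genes, the earliest to be transcribed by the embryo, were also higher, with a median of 0.14 over 26 members of which 19 lay above 0 and 2 rose (0.64 and 10 with a pseudocount of 0.1 RPKM, 0.03 and none with 5 RPKM, as most values were low). Among them klf17 rose from 0.739 to 3.12 RPKM and irx7 from 0.207 to 1.70 RPKM, and aplnrb, which codes for an apelin receptor, stood at 0.0968 and 1.12 RPKM.

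The largest rises at 2 hpf were in features without a symbol. ENSDARG00000089968 stood at 1.12 RPKM in control and 277.0 RPKM in knockdown embryos, and ENSDARG00000088951 at 1079 and 64408 RPKM. A set of 5 such features above 5000 RPKM took 45.1% of the RPKM sum of the knockdown table at 2 hpf, against 1.34% in control at 2 hpf, 0.776% in control at 6 hpf and 2.95% in knockdown at 6 hpf. The feature named 5_8S_rRNA, a piece of ribosomal RNA, was 11.6-fold higher by RPKM at 2 hpf, with 70.0 RPKM in control and 812.2 RPKM in knockdown embryos. The falls were smaller. They included sc:d217 (14.2 to 0.0710 RPKM), si:dkey-253d23.3 (8.14 to 0.511 RPKM), tmem45a (20.03 to 3.21 RPKM), spata2l (20.8 to 3.67 RPKM) and npdc1b (8.41 to 1.06 RPKM).

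The 24 gene lists were fixed before the data were examined, and 22 had at least 3 measured members. At 2 hpf 4 of these 22 had a median outside the middle 95% of 10000 random lists matched on size and mean expression, where 1.1 would fall outside by chance. Besides the ribosomal protein and first-wave lists, these were the 13 transcripts of the mitochondrial genome, read as a measure of RNA quality and all above 0 with a median of 0.14 (MT-ND6 at 738.1 and 907.3 RPKM), and the enveloping layer list, whose median was 0.01. Quantile normalization brought the last 2 inside (medians 0 and 0.01), and a filter of 5 RPKM brought the enveloping layer list inside. Known maternal transcripts lay inside the range, with a median of -0.08 over 26 members that became 0.11 after rescaling by the median ratio. Of these, org, an oogenesis-related gene, rose from 180.6 to 369.9 RPKM, and DAZL, a germ cell RNA-binding protein gene, stood at 102.1 and 150.8 RPKM. The stress list was inside the range too, although its member sesn2, a sestrin gene, rose from 6.48 to 29.1 RPKM and HSPB1 fell from 3.10 to 0.976 RPKM. The germ cell list (median -0.20) was inside, as were the mRNA decay list (-0.10, and 0.09 after rescaling by the median ratio), the cell cycle list (-0.11 and 0.07) and the p53 list (-0.08 and 0.06), and no member of these 4 lists passed 2-fold. The median log2 ratio over the 10479 genes at 1 RPKM or more in all 4 tables was -0.18 at 2 hpf and 0.28 at 6 hpf, and rescaling by the median ratio shifted these medians by 0.18 and -0.19, which gave 125 rises and 100 falls at 2 hpf, against 129 and 93 with quantile normalization and 58 and 4453 with a rescaling to equal RPKM sums. That last rescaling, which the 5 features above dominate, turned the ribosomal protein median to -0.35 and the mitochondrial one to -0.62, both still above their random ranges, and the enveloping layer median to -0.0024, inside it.

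At 6 hpf maternal transcripts were higher and many zygotic transcripts lower in knockdown than in control embryos. In total 1414 genes had risen and 1277 had fallen. Known maternal transcripts were higher, with a median log2 ratio of 0.91 over 26 members, 11 of which rose and none of which fell. Examples were GDF9, an oocyte growth factor gene (2.54 RPKM in control, 12.8 RPKM in knockdown), buc, the organizer of the germ plasm (14.97 and 48.2 RPKM), and pabpn1l, which codes for a poly(A)-binding protein (29.5 and 94.5 RPKM). Markers of the enveloping layer, the outer epithelium of the early embryo, were lower, with 13 of 17 members fallen, none risen and a median of -1.59. Its members krt17 (52.6 and 3.53 RPKM), agr1 (22.6 and 1.02 RPKM) and cyt1l (49.8 and 6.36 RPKM) fell most, although reads shared among keratin genes leave single keratins uncertain.

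Lists of the signals that pattern the germ layers were lower together at 6 hpf. The random lists for these were matched on mean expression and not on the change over time. All genes with a log2 change over time (mean of both arms) of 3 to 4 had a median of -0.48 at 6 hpf. Those above 4 had one of -0.61, with a lower quartile of -1.43. The Nodal and neurectoderm medians are therefore not shown to go beyond those of other late-rising genes. Whether the BMP, FGF, Wnt, yolk syncytial layer and enveloping layer medians go beyond them was not tested. Of the Wnt list 5 of 9 members fell and none rose (median -1.32), led by cdx4, a caudal homeobox gene, at 69.9 RPKM in control and 2.80 RPKM in knockdown embryos, by msgn1, a regulator of presomitic mesoderm (56.4 and 4.64 RPKM), and by the Wnt feedback inhibitor NKD1 (8.30 and 1.02 RPKM). Of the FGF list 6 of 10 members fell and none rose (median -1.20), among them the ligand gene fgf24 (7.52 and 1.76 RPKM) and the feedback inhibitors SPRY4 (15.06 and 5.004 RPKM) and SPRY2 (32.4 and 11.5 RPKM). The BMP and ventral list had 6 of 13 members fallen and none risen (median -0.94), with eve1 at 85.5 and 8.93 RPKM and krt5 at 701.4 and 127.3 RPKM. In the Nodal and mesendoderm list 8 of 21 members fell and none rose (median -0.65), with mespaa at 18.1 and 0.626 RPKM and mespab at 19.4 and 1.37 RPKM. The yolk syncytial layer list, from the tissue that feeds yolk to the embryo, had 5 of 6 members fallen (median -1.55, and -0.90 over 10 members with no filter on low values), including the lipid transfer gene MTTP (66.4 and 16.3 RPKM), SLC26A1 (31.9 and 10.1 RPKM) and apoa2 (3.75 and 0.203 RPKM). Some genes stand in more than 1 list, and the Wnt list shared 2 members with the Nodal list and 1 each with the BMP and neurectoderm lists.

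Zygotic genes did not all go the same way. In the neurectoderm list (median -0.58 over 7 members) SOX2, a neural and pluripotency factor, fell from 44.8 to 2.18 RPKM, whereas her5 rose from 7.41 to 39.4 RPKM. The first-wave list was inside its random range, with a median of -0.07, 3 rises and 6 falls among 26 members, and apoeb fell from 1678 to 405.0 RPKM. The germ cell list was higher (median 0.66, 3 of 14 members risen, none fallen), with gra at 25.8 and 63.6 RPKM and PIWIL2 at 4.36 and 10.4 RPKM, and it shared 5 members with the maternal list. All genes with a log2 change over time of -3 to -2 had a median of 0.66 at 6 hpf too. Those of -2 to -1 had one of 0.57, so the germ cell list is not shown to go beyond other falling transcripts. Ribosomal protein transcripts were lower (median -0.68 over 70 members, 2 of them above 0, 5 fallen, or 22 after rescaling by the median ratio), with RPL10A at 270.3 and 125.4 RPKM and RPL5 (ENSDARG00000020197, 1 of 2 identifiers with this symbol) at 188.3 and 87.3 RPKM. Transcripts of the mitochondrial genome were higher, with a median of 0.44 (0.23 after rescaling by the median ratio) over 13 members, 12 of them above 0 and none past 2-fold; mt-atp8 stood at 25.6 and 48.6 RPKM.

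Other lists lay inside their random ranges at 6 hpf, although single members moved. Of the activators of the zygotic genome (median -0.10, and 0.008 with quantile normalization), nanog rose from 207.5 to 728.0 RPKM and pou5f3 stood at 706.7 and 674.6 RPKM. In the mRNA decay list (median 0.09, and -0.13 after rescaling by the median ratio) the deadenylase gene CNOT8 rose from 61.6 to 217.9 RPKM and LSM14B from 28.6 to 80.6 RPKM, and none of the other 39 members rose or fell (igf2bp1 stood at 69.2 and 34.6 RPKM). Of the translation factors (median -0.05), EEF2K (2.40 to 0.591 RPKM) and eef1a1l1 (3941 to 1948 RPKM) fell and EIF2B5 rose from 7.66 to 16.4 RPKM. In the cell cycle list (median 0.22, and -0.0013 after rescaling by the median ratio) 4 of 38 members rose, including GMNN, an inhibitor of DNA replication licensing (91.4 to 298.2 RPKM), and WEE2 (28.3 to 82.1 RPKM), and 2 fell, 1 of them BUB3 (52.8 to 18.2 RPKM). The p53 list, read as a sign of the off-target response known for morpholinos, had no member risen and 4 of 19 fallen (median -0.01, and 0.04 with no filter on low values), with CCNG2 at 65.6 and 13.2 RPKM, sesn3 at 234.1 and 75.9 RPKM and PERP at 93.4 and 31.7 RPKM. The interferon list had a median of -0.05, with tnfb at 3.55 and 1.03 RPKM and gbp1 at 1.799 and 4.98 RPKM. Among the heat shock and stress genes 7 of 23 fell and 1 rose (median -0.16, inside the range but below it with a pseudocount of 5 RPKM, with no filter, with a filter of 5 RPKM and, at -0.38, after rescaling by the median ratio), and the falls were led by hsp70.3 (145.9 to 11.5 RPKM) and hsp70.1 (22.4 to 1.45 RPKM), members of a family that can share reads. Genes used by every cell had a median of -0.18 that became 0.02 with quantile normalization, and of these TBP rose from 44.9 to 117.3 RPKM and tuba1b fell from 4.78 to 1.21 RPKM. The DEAD-box helicase list had a median of 0.36 over 9 members, and the follicle list had 3 measured members with a median of 0.56, of which zp3c rose from 8.88 to 25.9 RPKM. No member of the erythroid and the muscle and neuron lists reached 1 RPKM, with highest values of 0.371 and 0.408 RPKM.

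**Figure D1:**
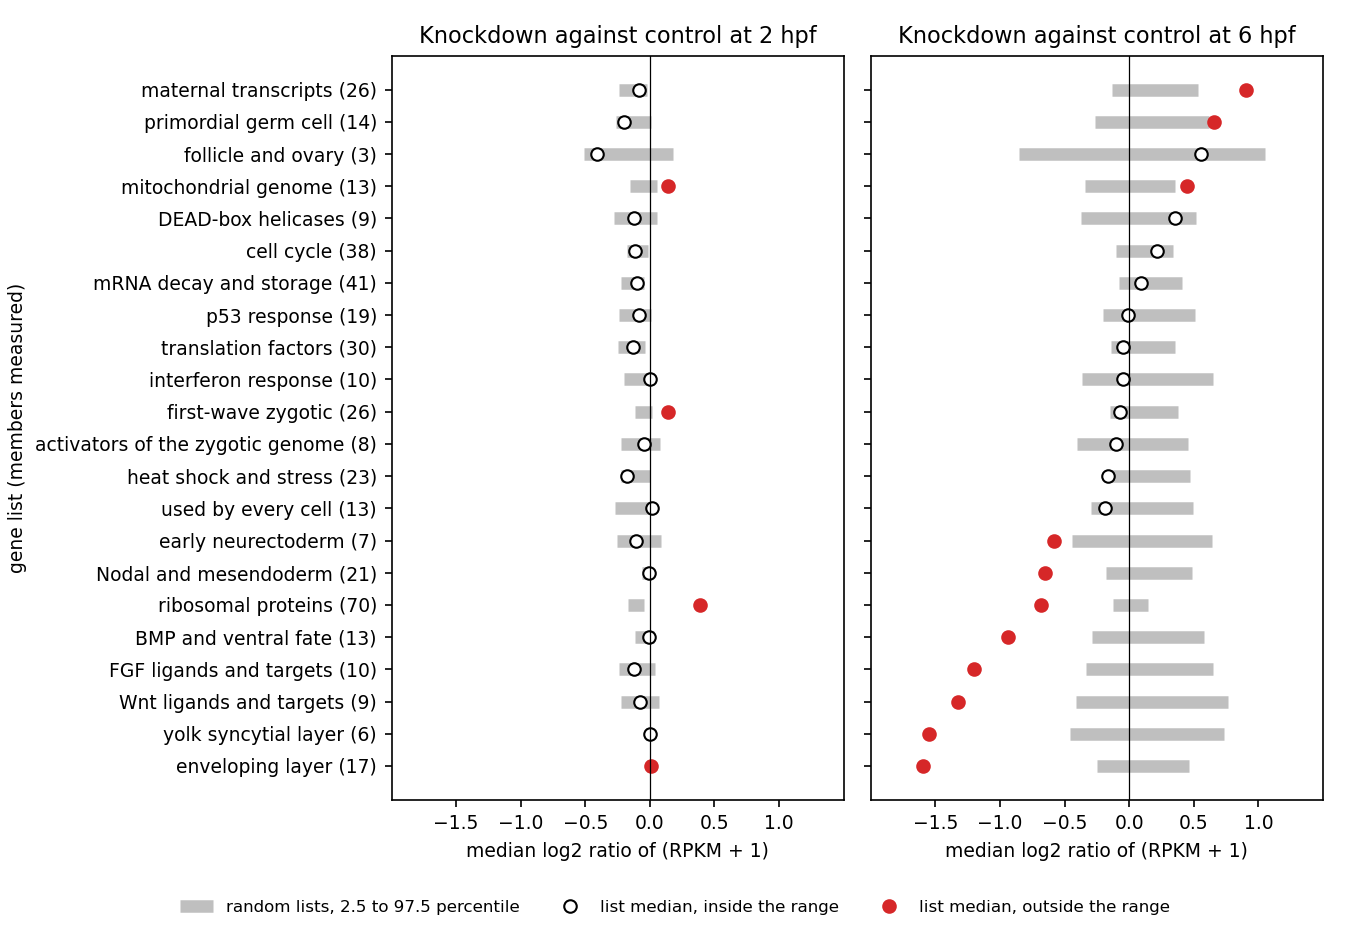
Median log2 ratio of (RPKM + 1), knockdown over control, of 22 gene lists at 2 hpf (left) and 6 hpf (right), with the number of measured members in brackets. Filled points lie outside the middle 95% of 10000 matched random lists (grey bars): 11 at 6 hpf, from -1.59 for the enveloping layer to 0.91 for maternal transcripts, and 4 at 2 hpf, of which the enveloping layer, ribosomal protein and mitochondrial medians turn negative with equal RPKM sums, while many open points at 2 hpf turn positive after rescaling by the median ratio.

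The largest single falls at 6 hpf included cdx4, si:ch211-217k17.9 (93.0 to 3.26 RPKM), HSP90AA1 (230.3 to 14.3 RPKM), PLA2G12B (38.5 to 1.64 RPKM), the gluconeogenic gene pck2 (58.5 to 3.07 RPKM) and EGLN3, a prolyl hydroxylase gene of oxygen sensing (228.6 to 14.8 RPKM). The largest rises were smaller, with ENSDARG00000083906 at 1.30 and 20.7 RPKM, znf1089 at 4.71 and 39.1 RPKM and zgc:171717 at 0.418 and 8.63 RPKM. Past 4-fold there were 292 falls and 47 rises. Of the 22 lists 11 had a median outside the random range, 3 above and 8 below, and none of these 11 medians changed sign under another scaling, pseudocount or filter. A pseudocount of 5 RPKM brought the maternal median to 0.59, the FGF median to -0.80 and the Wnt median to -0.73. The neurectoderm list came inside the range (median -0.13) with no filter on low values, and the germ cell list with a pseudocount of 5 RPKM (median 0.43) or a filter of 5 RPKM (median 0.66). The split of rises and falls depended on the scaling, with 826 and 1721 after rescaling by the median ratio and 1039 and 1498 with quantile normalization.

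**Figure D2:**
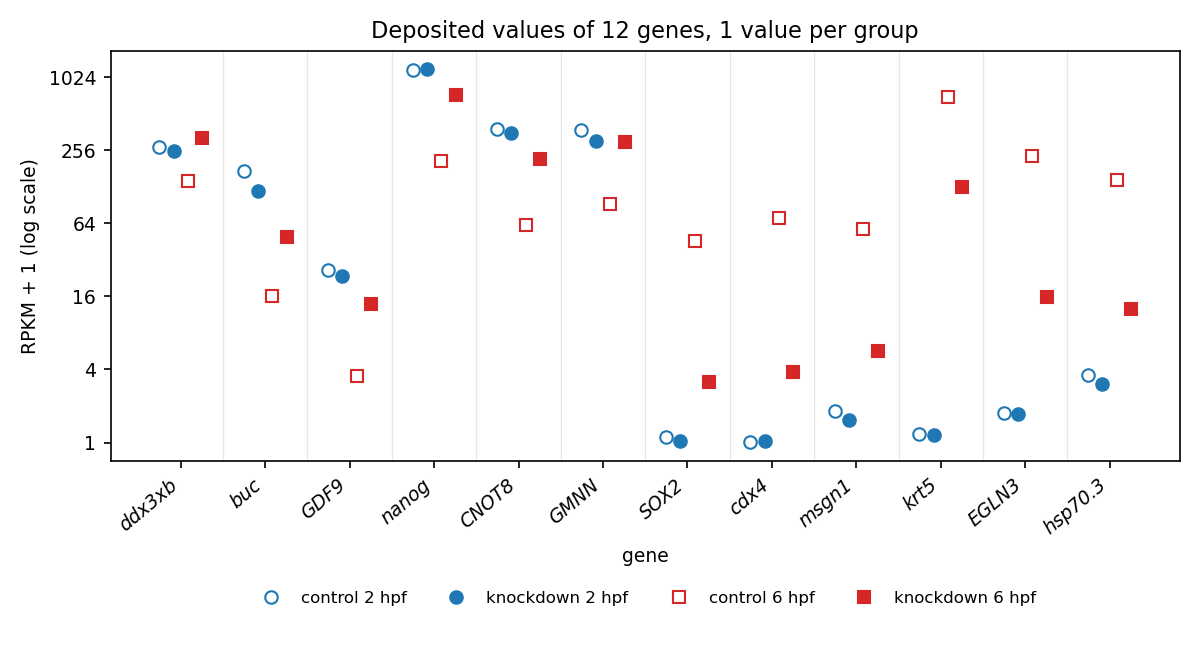
Deposited RPKM + 1, on a log scale, of ddx3xb, maternal genes (buc, GDF9, nanog, CNOT8, GMNN), zygotic genes (SOX2, cdx4, msgn1, krt5) and genes of the stress and oxygen responses (hsp70.3, EGLN3). Each point is the value of 1 group: the paired circles of 2 hpf lie close together, and at 6 hpf knockdown lies above control for the maternal genes shown (buc 48.2 against 14.97 RPKM) and below it for the zygotic ones shown (cdx4 2.80 against 69.9 RPKM). The genes were picked from those named in the text, most of them drawn for large ratios, and do not stand for their kind. The zygotic gene her5, not shown, went the other way (39.4 against 7.41 RPKM).

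Genes that rose or fell at 2 hpf overlapped with those at 6 hpf in part. Of the 82 genes higher at 2 hpf, 28 were also higher at 6 hpf, where independent lists would share 7.15, and 3 were lower (6.46). Only 34 of the 82 had a symbol, and the 28 include 5_8S_rRNA and the 5 features above 5000 RPKM. The numbers for independent lists count all 16217 genes, although genes with low values at 2 hpf can hardly pass 2-fold there. Of the 153 genes lower at 2 hpf, 26 were lower at 6 hpf (12.05) and 7 were higher (13.3). Across all genes the effects at both ages were hardly related, with a Pearson correlation of 0.0068 and a Spearman correlation of -0.06, and genes are not independent replicates.

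Genes were then classed by their own course from 2 to 6 hpf, taken as the mean of both arms so that neither table of an age enters the class more than the other. The 699 cleared genes, present at 2 hpf and at least 4-fold lower at 6 hpf, had a median log2 ratio of 0.65 at 6 hpf (quartiles 0.29 and 0.96), and 152 of them rose while 2 fell. The 1308 activated genes, near absent at 2 hpf, had a median of -0.42 (quartiles -1.33 and 0.22), with 418 fallen and 81 risen. The 2515 stable genes had a median of 0.28, with 174 risen and 31 fallen. At 2 hpf, where low values hold activated genes near 0, the cleared, activated and stable medians were -0.10, 0 and -0.18, and the first and the last became 0.09 and 0.006 after rescaling by the median ratio. Across all genes the mean change over time and the knockdown effect at 6 hpf had a Spearman correlation of -0.51 (Pearson -0.49), against 0.08 (0.04) at 2 hpf. Setting the classes from the control tables alone gave 0.81 and -0.75 for cleared and activated genes at 6 hpf. Setting them from the knockdown tables alone gave 0.36 and -0.15, with the stable class at 0.41, above the cleared class.

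**Figure D3:**
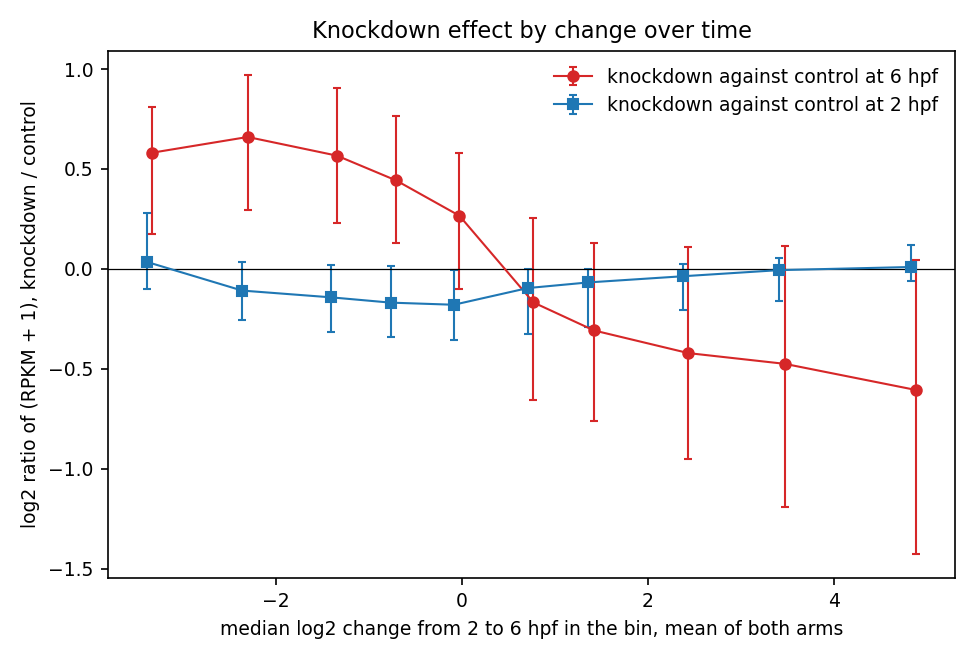
Median log2 ratio of (RPKM + 1), knockdown over control, at 6 hpf (circles) and 2 hpf (squares) in bins of genes ordered by their log2 change from 2 to 6 hpf (mean of control and knockdown), with bars for the quartiles of each bin. At 6 hpf the bin medians run from 0.66 among genes that fell over time to -0.61 among those with the largest increase, while at 2 hpf they stay between -0.18 and 0.03.

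The change from 2 to 6 hpf in control embryos was far larger than either knockdown effect, with 4453 genes risen and 4547 fallen. The largest rises were in keratin genes of the enveloping layer and in apoeb: krt18a.1 went from 0.0773 to 1268 RPKM, krt4 from 0.0872 to 1065 RPKM and apoeb, an apolipoprotein gene, from 0.539 to 1678 RPKM. Large falls were seen for maternal transcripts such as micall2b (212.1 to 9.81 RPKM), zgc:163014 (123.6 to 5.05 RPKM) and slbp2, which codes for a histone mRNA-binding protein of the oocyte (125.5 to 6.94 RPKM). All 26 first-wave genes rose (median log2 ratio 6.00), as did all 17 enveloping layer genes (5.85) and 67 of 70 ribosomal protein genes (2.27), while 17 of 26 known maternal transcripts fell and 1 rose (-1.95). Of the 22 lists 17 lay outside their random ranges.

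In knockdown embryos the same interval brought 4132 rises and 2107 falls. The same keratins led the rises to lower levels, with krt18a.1 at 506.1 RPKM and krt4 at 351.8 RPKM at 6 hpf. The maternal list had a median of -0.64, with 10 members fallen and 4 risen, and the first-wave list one of 5.33 with all 26 members risen. Of the genes that rose in control embryos 3191 (71.7%) also rose in knockdown embryos, and of those that fell in control embryos 1900 (41.8%) also fell. Among named falls ITM2C went from 96.4 to 3.33 RPKM, and most of the other large falls were in the features without a symbol that stood high at 2 hpf. With tables rescaled to equal RPKM sums the knockdown counts became 6647 rises and 1060 falls. Falls in control and knockdown numbered 3890 and 2680 after rescaling by the median ratio and 4035 and 2577 with quantile normalization. With equal sums without the features above 5000 RPKM they numbered 5525 and 3108. The shares of 71.7% and 41.8% are those of the deposited scaling.

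The difference between the effects at 6 and 2 hpf was at least 2-fold upward for 2676 genes and downward for 1283. It was positive for the maternal list, with 13 of 26 members past 2-fold upward and none downward, and for cleared genes (0.72). It was negative for the Wnt list (-1.60), the enveloping layer (-1.57), the yolk syncytial layer (-1.52), ribosomal proteins (-1.06, 42 of 70 members past 2-fold) and activated genes (-0.42). As 1 value stood for each group, no interaction could be tested. The split was 1076 and 1910 after rescaling by the median ratio, 1319 and 1722 with quantile normalization, and 8053 and 1175 with equal RPKM sums.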

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

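The tests of scaling, ribosomal RNA carry-over and stage for the first pattern, of scaling and of the 2 hpf percentile for the second, and of dilution for the third were chosen only after the result was seen. A difference between the 2 ages singled out 2 lists that lay above their random range at 2 hpf and below it at 6 hpf. The enveloping layer list stood at 0.0102 at 2 hpf and -1.59 at 6 hpf, and its 2 hpf place was inside the range with a filter of 5 RPKM (percentile 89.7), quantile normalization (97.1) or equal RPKM sums (62.7). The other was the ribosomal protein list, at 0.39 and -0.68. Neither difference between ages was tested.

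At 6 hpf cleared genes were higher and activated genes lower in the knockdown, with a gap between their medians of 1.08. A single scaling factor cannot open such a gap. Setting the classes from the knockdown tables alone left 0.51 of it (1.56 from the control tables alone). Double use of the control values, in the classes and in the effect, therefore does not account for all of it. With 1 value per group, a chance difference between the tables that many genes share cannot be excluded. Carry-over of ribosomal RNA stays open: cleared genes lay 0.0841 above stable genes at 2 hpf, where 5_8S_rRNA differed more, and 0.37 above them at 6 hpf, but with classes from the knockdown tables alone these differences were 0.15 and -0.0494. Embryos collected at an earlier stage could give the same picture, since the effect ran against the change over time across genes (Spearman -0.51), and a delay brought by the knockdown could not be told apart from one brought by collection. The first-wave list was higher, not lower, at 2 hpf (median 0.14), although low values left little room for a fall at that age.

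Ribosomal protein transcripts were higher at 2 hpf and lower at 6 hpf. After rescaling by the median ratio the medians were 0.58 and -0.90, while equal RPKM sums, which the 5 largest features dominate, put the 2 hpf median at -0.35, so the sign at 2 hpf depends on the scaling, and the place above random lists (percentile 100) held under each of these. Short length stays open as a cause: nuclear genes of the respiratory chain, meant as another set of short transcripts, had medians of -0.11 at 2 hpf and -0.19 at 6 hpf over 82 members, but gene lengths are not given in the sources used here and long genes are among them, so they do not test it. A late start of ribosomal protein genes stays open for the 6 hpf part. Members with the larger change over time had the lower effect (Spearman -0.63 over 70 members). Both values use the 6 hpf tables, and all genes gave -0.51. The correlation therefore does not tell a late start of this list from the general trend. A late start would leave the 2 hpf part without a cause, since there the list lay at percentile 100 of random lists.

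The feature 5_8S_rRNA and features without a symbol were far higher in the knockdown table at 2 hpf. Features named 5S_rRNA had a median ratio of 1 there, but 9 of 11 were at 0 in both tables. The only one above 1 RPKM at 2 hpf, ENSDARG00000085561, went the other way, with 17.9 RPKM in control and 8.32 RPKM in knockdown embryos. With a single readable feature, carry-over of all ribosomal RNA through the poly(A) selection could be neither shown nor excluded. Dilution of all other genes stays open: mitochondrial and ribosomal protein transcripts had medians of 0.14 and 0.39, against its direction, while the median of genes present in all 4 tables was -0.18, in its direction. Whether these features differ between the 2 libraries of the group is unknown, as 1 value stands for both.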

How the results depend on the processing

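The rescaling to equal sums without features above 5000 RPKM was chosen only after the result was seen. Of 1716 values recomputed under an alternative 1000 stayed within the limits set for sameness; of 1600 log2 ratios and medians 48 came to lie on the other side of 0, 4 of them among the main results (ddx3xb, cleared genes under 2 alternatives, and stable genes, all at 2 hpf). With a pseudocount of 0.1 RPKM, 287 genes rose and 582 fell at 2 hpf, 2875 and 1925 at 6 hpf, the difference between ages was upward for 4375, cleared and activated medians were -0.12 and -0.0168 at 2 hpf and 0.84 and -0.56 at 6 hpf, and the cause was not tested for the medians, while the counts grow because a smaller pseudocount widens ratios at low values. With 5 RPKM, which narrows them, counts were 33 and 19 at 2 hpf, 459 and 539 at 6 hpf, 2374 and 2641 over time in control, 2119 and 1194 in knockdown, and 974 and 594 for the difference. A filter of 5 RPKM left 96 falls at 2 hpf, from fewer genes, and put the enveloping layer list inside and the neurectoderm list (median 0.23) above its range there; genes used by every cell came above theirs with no filter (0.02) and after rescaling by the median ratio (0.22). Rescaling by the median ratio gave 125 rises and 100 falls at 2 hpf, 826 rises at 6 hpf and 1076 upward differences, put ddx3xb at 0.0689 and 0.97 at the 2 ages, turned the cleared and stable medians at 2 hpf to 0.0918 and 0.00597, and gave 0.50, -0.62 and 0.0709 for cleared, activated and stable genes at 6 hpf, all by its shift of each age. Quantile normalization gave 129 and 93 at 2 hpf and 1319 upward differences, with 2 lists outside at 2 hpf; the cause was not tested. Rescaling to equal sums, which the 5 largest features dominate, gave 4453 falls at 2 hpf, 6647 and 1060 over time in knockdown, 8053 upward differences, -0.89 for ddx3xb at 2 hpf, and turned the enveloping layer, ribosomal protein and mitochondrial medians at 2 hpf to -0.0024, -0.35 and -0.62. Without those features it gave 175 and 230 at 2 hpf, cleared and stable medians of -0.0303 and -0.12 at 2 hpf, and 0.72, -0.50 and 0.24 for cleared, activated and stable genes at 6 hpf; the cause was not tested. At 1.5-fold, by the lower threshold, counts were 284 and 1050 at 2 hpf, 4237 and 2633 at 6 hpf, 3714 falls over time in knockdown, and 5974 and 2428 for the difference. At 4-fold they were 28 and 13, 47 and 292, 2164 and 1396 over time in control, 1691 and 419 in knockdown, and 116 and 297 for the difference. Classes from the control tables gave -0.16 for cleared genes at 2 hpf and 0.81, -0.75 and 0.17 for cleared, activated and stable genes at 6 hpf. Classes from the knockdown tables gave -0.0058 for cleared and -0.16 for stable genes at 2 hpf and 0.36, -0.15 and 0.41 at 6 hpf. Classes at a log2 change of 1 gave -0.13 and -0.0044 for cleared and activated genes at 2 hpf, and at 3 they gave 0.0348 and 0.0039, with 0.58 and -0.56 at 6 hpf; for all class choices the cause was not tested. No paired analysis was possible because each table held 1 value per gene for both libraries of a group, and for the same reason leaving out each library, a fit of 2 groups alone, a replicate block and a list test with an estimated correlation were not run. Among the low-value genes used to read it, an RPKM of 5 stood for about 212 reads or more at the median read worth. At the 90th percentile of their read worth it stood for 39.6 reads in the shallowest group. Low values of genes with a high read worth carry the largest counting error.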

Other observations

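The tests on the low-oxygen and segmentation genes were chosen only after the result was seen, in the form given here. A list of genes of the response to low oxygen had a lower median in the knockdown at 6 hpf, but its members were divided. Of 47 symbols asked, 15 genes were compared. EGLN3 was among the largest falls, and 14 further genes outside the lists fixed beforehand had a median of -0.87. Of these 14, 7 had fallen and 3 lay above 0, 1 of them risen. ANKRD37, a target of the hypoxia-inducible factor, fell from 114.6 to 11.3 RPKM, P4HA2, a collagen prolyl hydroxylase gene, from 69.3 to 6.51 RPKM, EGLN2 from 8.62 to 0.438 RPKM and vhl, whose product marks the factor for breakdown, from 21.7 to 2.48 RPKM, while VLDLR rose from 8.30 to 19.01 RPKM. At 2 hpf their median of -0.22 lay inside the random range. The same list with GAPDH, its member in a fixed list (74.3 RPKM in control and 122.1 RPKM in knockdown), had a median of -0.57 at 6 hpf. Of the 7 that fell, 6 also rose over time (mean of both arms), such as P4HA2 and ANKRD37, whereas none of PDK1, higd1a, kdm3b, MXI1 and DDIT4, which hardly changed over time, fell, although MXI1 (-0.57) and DDIT4 (-0.55) were lower. The median of -0.87 also lay below random lists matched on the change over time (percentile 0). That change is the mean of both arms and holds the knockdown value at 6 hpf, so a member's own fall lowers it. The matching therefore cannot exclude the general trend of late-rising genes. Whether the fall belongs to the low-oxygen response as a group or to the timing of these members stays open, as does stage; the labels do not tell whether dishes differed in warmth or oxygen, and 7 of 23 heat shock and stress genes fell too.

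A list of genes of the presomitic mesoderm and its segmentation clock had a lower median at 6 hpf as well, but its members were divided. The 10 members outside the lists fixed beforehand had a median of -0.85, with 5 fallen, none risen and 3 above 0. At 2 hpf their median was -0.08, inside the random range. Among them pcdh8, a protocadherin gene, fell from 24.9 to 3.70 RPKM and HES6 from 75.2 to 15.05 RPKM. WNT3A fell from 1.77 to 0.188 RPKM and snai1a from 234.7 to 112.9 RPKM. The 3 above 0 were DLD (41.8 and 69.0 RPKM), LFNG (38.7 and 48.2 RPKM) and her11 (7.99 and 11.5 RPKM), so the clock genes as a whole are not shown to be lower. With the 2 members that stand in fixed lists the median was -1.07. At 2 hpf pcdh8 and HES6 were below 1 RPKM in both arms, and against random lists matched on the change over time the median lay at percentile 2.32, near the edge of the range, so the value of -0.85 may come in large part from the general trend of late-rising genes.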
